A study of Caenorhabditis elegans with 3 samples.

How the data were processed

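RNA from Caenorhabditis elegans, a free-living nematode, was measured on 3 arrays with 2 channels each. Per the labels, channel 1 of every array held a wild-type mixed reference RNA and channel 2 held RNA of late young adult hermaphrodites from preparation 1, 2 or 3; these preparation numbers were used as replicate numbers. The labels do not say which stages the reference mixed, which dyes were used, or whether the preparations came from separate cultures. The limma p-values of single genes therefore measure the spread between these preparations, which may be partly technical. Each array's label carries its own date, so array day and preparation cannot be told apart. The arrays correlated at r = 0.763 to 0.900 across genes, so no array repeated another.

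The deposited table holds 1 log2 ratio per probe and array, for 20000 probes. Its unit was settled from the values: for 99.98% of the deposited log2 values, 2 raised to the value was a whole multiple of 0.001 (within 0.01 of that step), against 3.35% with the sign turned, 2.38% for base e and 2.35% for base 10. The table is therefore the base-2 logarithm of a ratio kept to 3 decimals. How the authors background-corrected, normalized and filtered the arrays is not given in the sources used here. The array medians of the deposited log2 ratios were 0.05, 0.01 and 0.02, so the values were already close to centred. Such ratios compare shares of the RNA, not amounts per animal or per cell, so "higher" and "lower" are meant in this sense. The direction of the ratio is not stated. It was taken as likely channel 2 over channel 1, that is adult over reference, because the labels list the adult RNA as channel 2; the whole steps show only that the sign was not turned after the ratio was formed. If the direction were the other, every "higher" would read "lower". The fixed lists argue against that: 21 of 23 oocyte and eggshell genes lay above 0 and past the threshold, with 0 below. Of 89 moulting and epidermal matrix genes, 48 lay below 0 and past it, with 2 above. The other direction would give adults less oocyte RNA and more moulting RNA than the mixed reference. The make-up of that reference is not given, so the direction remains an inference. No spot intensities were used here, so faint and bright spots cannot be told apart, and precision is limited by the number of arrays.

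Of the probes, 19711 had a value on all 3 arrays, 183 on 2, 80 on 1 and 26 on none. Gene names came from the platform annotation given with the series, checked by gene identifier against a RefSeq gene table of the assembly WBcel235, which was used for names only. A single symbol was found for 15655 probes (15569 through the gene identifier, 7 through an accession and 79 by the annotation's symbol alone), 198 probes had several symbols and 4147 were not listed and are unnamed here. Probes of the same symbol were averaged on each array. Among 428 genes with several measured probes the means differed by a median of 0.24 on the log2 scale, by over 1 in 10 genes, and in no gene were probes beyond 2-fold in opposite directions. Probes with no symbol or several were kept under their own number. This left 19264 genes or unnamed probes measured on all 3 arrays, 15081 of them with a symbol. Genes with near-identical copies (major sperm proteins, collagens, histones, vitellogenins, actins) may share signal between probes, and their single values are uncertain.

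The log2 ratios as deposited were tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit with an intercept, then eBayes), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The reference RNA stands on every array, so its own spread does not enter this test, and the adult RNA is in channel 2 throughout, so an effect of the channel on a gene cannot be told from a difference. Fixed gene lists were tested with limma's camera with its preset correlation of 0.01 between genes, which sets a list against all other genes. Its p-value rests on the spread between genes and on that preset, so it does not measure agreement between preparations. A shift shared by all genes and arrays cancels only in part, because camera compares test statistics and not mean ratios. The 25 lists with at least 3 measured members were adjusted together. Camera with an estimated correlation and fry, which tests a list by itself against 0, were alternatives. With an estimated correlation, drawn from 3 arrays, no list passed (smallest adjusted p = 0.218, 3 lists at an unadjusted p under 0.05), and fry called 10 lists. That setting tests each list on the few degrees of freedom that 3 arrays leave, so it could hardly pass a list after adjustment. The P granule list had an estimated correlation of −0.00764, below the preset, yet its unadjusted camera p went from 7.90e-14 to 0.0142. A failure there does not by itself show that correlation between genes undoes a result. For some lists the estimate was far above the preset, such as 0.789 for the major sperm proteins and 0.612 for the ribosome. The preset p of such lists may be far too small. The lists hold 1933 distinct measured genes, 10 of them in more than 1 list, and 75 listed names had no probe with that symbol.

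Before the data were examined, the test, the lists, the alternatives and the rule for naming genes were fixed. The rule takes the 10 genes with a symbol that lay highest and the 10 that lay lowest among those past the threshold with the same sign on all arrays, and in each list the 3 members with the largest mean log2 ratio in size among those past the threshold. Genes named outside this rule are said to be so. On data simulated for this comparison (19264 genes, spreads drawn from the real ones), 100 genes were changed by 1 and 100 by 2 on the log2 scale; the test recovered 2% of the former and 56% of the latter, with 2 unchanged genes among 60 calls. A further simulation had as many changed genes as were called here, with their fitted ratios taken as true and independent noise. The test recovered 73.4% of those between 0.5 and 1, 93.5% of those between 1 and 2 and 98.9% of those from 2. Of its calls, 3.47% were false. These true ratios had been selected by the same test, and no array effects were shared between genes. Recovery may therefore be too high and the share of false calls too low. Alternatives were centring, scaling and quantile normalization of the arrays, other filters, each probe on its own, robust and unmoderated tests, other thresholds, other list tests and leaving out each replicate. Quality weights for the arrays, centring on the chemoreceptors and taking out the mean of neighbouring probes were added after seeing the data. Values are given as mean log2 ratio ± SD over the 3 arrays, and the spread of a list as the SD of its 3 array medians.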

Results

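Expression was measured in late young adult hermaphrodites of C. elegans, the self-fertile sex, against a mixed wild-type reference RNA on 3 arrays, 1 for each RNA preparation. The series holds 1 group of 3 samples, and the comparison its design implies is adult RNA over reference RNA; a ratio above 0 is taken as likely higher in the adult. Array 1 gave values for 19913 probes and arrays 2 and 3 for 19833 each, of 20000. Across 19264 genes, arrays 2 and 3 correlated at r = 0.900 (Spearman's rho 0.858), array 1 and array 2 at 0.763 (0.684) and array 1 and array 3 at 0.773 (0.699); genes are not independent replicates. The median SD of a gene between arrays was 0.27 on the log2 scale, and its moderated 95% confidence interval reached a median of 0.39 to either side of the mean. The SD of the log2 ratios over probes was 0.79 on array 1, 0.87 on array 2 and 0.90 on array 3, and their median absolute deviation, scaled to a normal SD, was 0.66, 0.61 and 0.64.

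The question was how far late young adults differed from the mixed population. Of the genes with a symbol, irg-5, the collagen col-101 and ugt-22 lay highest in the adult RNA, and the collagen col-36, the small heat shock protein gene hsp-12.6 and the collagen rol-8 lay lowest. Germline genes were higher in the adult, with 23 of 24 P granule and germline RNA genes past the threshold (camera adjusted p = 6.58e-13; adjusted p = 0.218 with an estimated correlation). Neuropeptide and insulin-like genes were lower, with 70 of 97 past the threshold (camera adjusted p = 3.55e-18; adjusted p = 0.398 with an estimated correlation). By limma with Benjamini-Hochberg adjustment, 7393 of 19264 genes or unnamed probes passed the threshold, 38.4%. Of these, 3769 were higher in the adult and 3624 lower; with the direction turned, these counts change places. At least 2-fold differences were found for 1606 higher and 1693 lower genes. Of the called genes, 7377 had the same sign on all 3 arrays, against 12292 of all genes (63.8%). Independent signs would give 25%, but the arrays share a reference and a channel layout, so signs can match without an adult difference. A one-sample test without moderation, which has only the 3 values of each gene, called 0 genes after adjustment (smallest adjusted p = 0.0682), with 6188 at an unadjusted p under 0.05 against 8985 by limma.

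The gene that lay highest was irg-5, named as an infection response gene, at a mean log2 ratio of 4.87 ± 0.96 (SD, n = 3), 29.3-fold, with a limma adjusted p of 5.77e-05. The gene irg-8, of the same naming, reached 3.31 ± 0.25. Of 2 UDP-glucuronosyltransferase genes, which belong to an enzyme class of xenobiotic conjugation, ugt-22 reached 3.76 ± 0.58 and ugt-63 reached 3.28 ± 0.80. The collagens col-101 and col-143 lay at 3.87 ± 0.55 and 3.44 ± 0.62, and pud-2.1 at 3.64 ± 0.45. The remaining 3 were known by sequence name, C27C7.1 at 3.70 ± 0.35, T16G12.3 at 3.63 ± 0.19 and Y38E10A.14 at 3.37 ± 0.50. The lowest gene was the collagen col-36, at −5.07 ± 1.31, 33.7-fold lower, with a limma adjusted p of 9.40e-05. Next came hsp-12.6, a small heat shock protein gene, at −4.96 ± 0.53, and the collagen rol-8 at −4.82 ± 1.47. The C-type lectin gene clec-60 lay at −4.80 ± 0.93 and adh-1, named as an alcohol dehydrogenase, at −4.72 ± 1.26. The acyl-CoA synthetase gene acs-2 lay at −4.61 ± 1.18, F45D3.4 at −4.30 ± 0.25, col-158 at −4.28 ± 1.19, scl-2 at −4.13 ± 0.77 and the fatty acid and retinol binding protein gene far-7 at −4.11 ± 0.36. On array 1 most of these genes, in both directions, lay nearer to 0 than on arrays 2 and 3. The exceptions were irg-5, pud-2.1, adh-1 and far-7. The large SDs of col-36, rol-8 and col-158 reflect this. Over all probes the slope of array 1 on the mean of the others was 0.702, against 0.874 for array 2 on array 3.

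**Figure D1:**
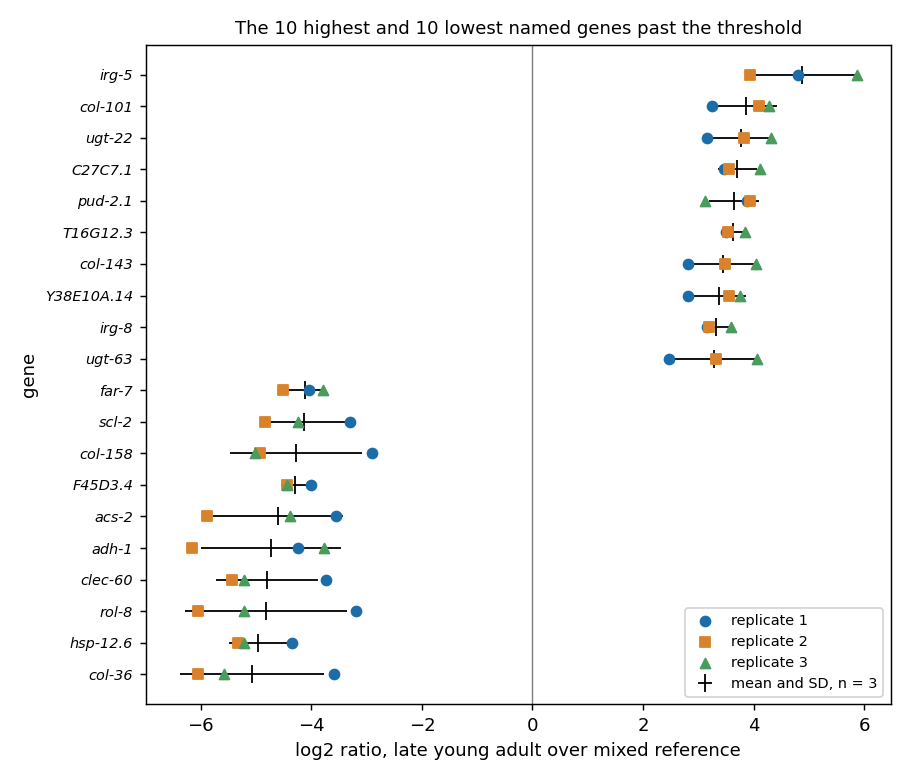
Log2 ratio of late young adult over mixed reference on each array (coloured points, 1 per replicate) for the 10 named genes that lay highest and the 10 that lay lowest among those past the threshold; black marks are the mean and SD, n = 3. irg-5 lies at a mean of 4.87 and col-36 at −5.07. The rule that picked these 20 genes required the same sign on all arrays, so their agreement in sign is no result.

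Germline genes were higher in the adult. Of 24 measured genes of P granules, the RNA-protein bodies of germ cells, and of germline RNA regulation, 23 were higher and 0 lower, with a median log2 ratio of 1.60 ± 0.22 (SD of array medians). The germline helicase genes glh-1, glh-2 and glh-4 led at 2.89 ± 0.29, 2.75 ± 0.06 and 2.49 ± 0.03. The 1 member that did not pass, named after its value was seen, was fog-3, a gene of the sperm fate decision, at 0.07 ± 0.02. Of 23 oocyte and eggshell genes, 21 were higher and 0 lower, with a median of 1.44 ± 0.03. The eggshell genes cpg-1 and cbd-1 lay at 2.48 ± 0.20 and 2.46 ± 0.12, and rme-2, the yolk receptor, at 2.32 ± 0.28. The other eggshell chondroitin gene cpg-2 and the oocyte surface gene egg-1, named after their values were seen, lay at −0.03 ± 0.15 and −0.31 ± 0.15 and did not pass. Of 25 meiotic chromosome genes, 23 were higher and 0 lower, with a median of 1.01 ± 0.03; the cohesins rec-8 and him-1 and the axis gene htp-3 led at 1.57 ± 0.13, 1.55 ± 0.35 and 1.5 ± 0.08. The counts adjusted over the list alone were equal to these, 23, 21 and 23. By camera the lists passed with adjusted p of 6.58e-13, 2.18e-10 and 1.09e-09; each gave adjusted p = 0.218 with an estimated correlation.

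Genes of DNA replication and of mitosis were higher as well. Of 25 replication genes, 20 were higher and 0 lower (21 and 0 adjusted over the list alone), with a median of 1.06 ± 0.02. The replicative helicase genes mcm-7, mcm-4 and mcm-2 led at 2.04 ± 0.24, 1.87 ± 0.30 and 1.78 ± 0.32. Of 37 genes of mitosis and the centrosome, 33 were higher and 0 lower (33 and 0 adjusted over the list alone), with a median of 1.21 ± 0.06. The kinesin gene klp-7 lay at 2.3 ± 0.74 and the kinetochore genes hcp-4 and hcp-1 at 2.06 ± 0.16 and 2.01 ± 0.32. Camera gave adjusted p of 1.09e-09 and 2.84e-13; both had adjusted p = 0.337 with an estimated correlation.

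The yolk protein list held 3 measured genes. vit-2 was higher at 1.28 ± 0.18, and vit-5 and vit-6, named after their values were seen, lay at 0.16 ± 0.47 and 0.26 ± 0.22 and did not pass. The count was 1 of 3 over all genes and adjusted over the list alone, and the list did not pass by camera (adjusted p = 0.205). Of 50 genes of the zygotic embryo, 5 were higher and 8 lower (5 and 7 adjusted over the list alone), with a median of 0.20 ± 0.03 and a camera adjusted p of 0.489. The skn-1-dependent zygotic genes sdz-24 and sdz-8 lay at −2.22 ± 0.26 and −1.26 ± 0.45 and sdz-6 at 1.33 ± 0.08. The other 4 that were higher, named after their values were seen, were pal-1, tbx-9, sdz-15 and sdz-10, at 0.62 to 0.88. Without array 1 the counts were 11 higher and 9 lower, and without array 2 they were 3 and 6. Of 15 genes of the male tail and male neurons, 0 were higher and 2 lower, cwp-4 at −0.81 ± 0.03 and mab-7 at −0.78 ± 0.09 (0 and 2 adjusted over the list alone; camera adjusted p = 0.378). Without array 1 the male list had 1 higher and 3 lower, and its median of −0.14 was −0.04 without array 3.

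Several lists ranked the arrays in the same way, with array 3 above array 2. A list of abundant housekeeping genes, written after this was seen and before its own values were looked at, was higher on array 3 than on array 2 by a median of 0.71 (95% bootstrap interval 0.57 to 0.82) in 38 of 38 genes, against a median of 0.02 over all named genes. The median of a list on array 3 minus that on array 2 was 1.21 for the major sperm proteins, 0.51 for other sperm genes, 0.64 for the ribosome, 0.58 for mitochondrial respiration, 0.86 for the adult cuticle, 0.61 for cuticle collagens, 0.68 for the pharynx and 0.46 for body wall muscle. It was −0.63 for the list of 3 yolk protein genes, the opposite direction, although vit-2 lay higher on array 3 than on array 2. Of 30 major sperm protein genes, which encode the main cytoskeletal protein of sperm, 28 were higher and 0 lower (29 and 0 adjusted over the list alone), with a median of 1.14 ± 0.61. The array medians were 1.09, 0.59 and 1.80. msp-50, msp-56 and msp-77 led at 1.55 ± 0.71, 1.53 ± 0.79 and 1.49 ± 0.71. Of 39 other genes of sperm function, 21 were higher and 1 lower (24 and 1 adjusted over the list alone), with a median of 0.56 ± 0.28. The translational regulator cpb-1 and spe-39 were higher at 1.48 ± 0.33 and 1.44 ± 0.13, and spe-27 was lower at −1.85 ± 0.46. Without array 3, 9 of these 39 genes were higher and 1 lower. Camera gave adjusted p of 4.27e-09 and 1.26e-05 for the 2 lists; both had adjusted p = 0.524 with an estimated correlation.

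Of 63 cytosolic ribosomal protein genes, 15 were higher and 2 lower (6 and 1 adjusted over the list alone), with a median of 0.33 ± 0.32, and array medians of 0.32, 0.08 and 0.72. rpl-11.1, rpl-23A.2 and rpl-4 led at 1.19 ± 0.32, 1.12 ± 0.12 and 1.1 ± 0.53, and the 2 that were lower, named after their values were seen, were rpl-11.2 at −0.63 ± 0.53 and rpl-23A.1 at −0.79 ± 0.51. The list passed by camera (adjusted p = 0.00133), had adjusted p = 0.775 with an estimated correlation, and did not pass without array 3 (adjusted p = 0.194). Without array 3 its median was 0.21 and its counts were 3 higher and 2 lower, and without array 2 they were 20 and 0. Of 31 genes of mitochondrial respiration, 9 were higher and 2 lower (8 and 2 adjusted over the list alone), with a median of 0.21 ± 0.29 and a camera adjusted p of 0.0930, which was 0.0122 without array 2. Without array 3 the median was 0.07, with 4 higher and 2 lower, and without array 2 it was 0.41, with 9 and 1. nuo-5, ucr-2.3 and asb-1 led at 1.39 ± 0.40, 1.25 ± 0.22 and 1.24 ± 0.27, and the 2 that were lower, named after their values were seen, were cox-6A at −0.92 ± 0.55 and cyc-2.1 at −0.59 ± 0.37.

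Cuticle collagens went both ways. Of 152 collagen genes, which build the exoskeleton that is renewed at each moult, 37 were higher and 62 lower (43 and 64 adjusted over the list alone), 29 and 52 of them by at least 2-fold. Their means ran from −5.07 for col-36 to 3.87 for col-101. The list's median was −0.28 ± 0.33, its array medians were −0.11, −0.64 and −0.03, and the camera adjusted p was 0.0484 in the lower direction. It had adjusted p = 0.790 with an estimated correlation, and 0.274 without array 2. Its median was −0.14 without array 2 and −0.44 without array 3. Of 5 genes of the adult cuticle, 3 were higher, col-19 at 2.75 ± 0.50, col-62 at 1.90 ± 0.75 and col-7 at 1.59 ± 0.66 (4 adjusted over the list alone). The list's median was 1.59 ± 0.66 and its camera adjusted p 0.00951, with adjusted p = 0.524 with an estimated correlation. Both collagen lists lay higher on array 3 than on array 2, as the housekeeping genes did. Of 89 genes of moulting and the epidermal matrix, 2 were higher and 48 lower (3 and 51 adjusted over the list alone), with a median of −0.64 ± 0.09. The cuticlin genes cut-1 and cut-3 lay at −3.97 ± 1.31 and −3.24 ± 0.81, and the hedgehog-related gene wrt-10 at −3.43 ± 0.91. The 2 that were higher, named after their values were seen, were ptr-2 at 2.03 ± 0.18 and nhr-23 at 1.14 ± 0.16; without array 1, 4 were higher and 54 lower. Camera gave 1.72e-10 for this list, with adjusted p = 0.390 with an estimated correlation.

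**Figure D2:**
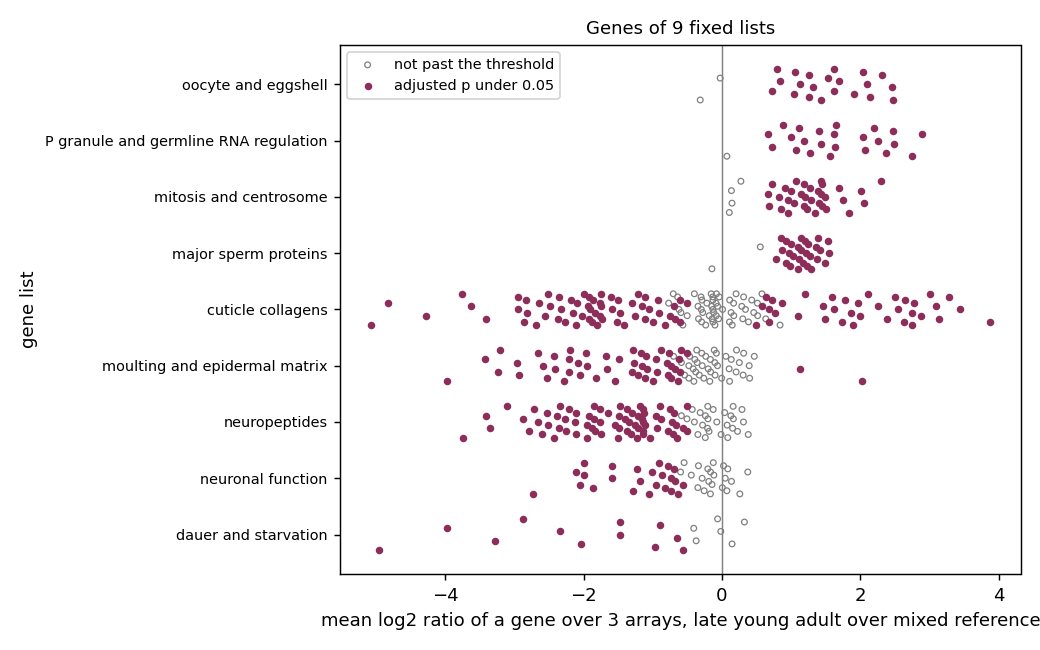
Mean log2 ratio over 3 arrays of every measured gene of 9 fixed lists (each point a gene; filled points passed the adjusted threshold of 0.05, open points did not; vertical scatter is only for display). The P granule list has 23 of 24 genes to the right of 0 and past the threshold, the neuropeptide and insulin-like list 70 of 97 to the left, and the cuticle collagens 37 to the right and 62 to the left.

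Neuronal genes were lower in the adult as a share of the RNA. A larger germline share in the adult could lower these ratios without a change within neurons. By itself it would lower somatic lists alike, yet the intestine, body wall muscle and somatic gonad medians were 0.05, −0.09 and −0.12. This argues against germline share as the only cause of the neuronal values. The pharynx and moulting medians were lower, at −0.35 and −0.64. How much a germline share adds cannot be told from the arrays. Of 97 neuropeptide and insulin-like genes, 70 were lower and 0 higher (70 and 0 adjusted over the list alone), with a median of −1.16 ± 0.22. flp-1, nlp-17 and nlp-80 lay at −3.75 ± 0.29, −3.41 ± 0.60 and −3.35 ± 0.33. Of 46 genes of neuronal function, 24 were lower and 0 higher (25 and 0 adjusted over the list alone), with a median of −0.62 ± 0.13. The dense-core vesicle gene ida-1, the GABA synthesis gene unc-25 and the synaptotagmin gene snt-1 led at −2.73 ± 0.36, −2.11 ± 0.45 and −2.06 ± 0.70. Camera gave adjusted p of 3.55e-18 and 2.29e-07; the values were adjusted p = 0.398 and adjusted p = 0.524 with an estimated correlation. Among 975 chemoreceptor genes, 21 were higher and 27 lower (0 and 2 adjusted over the list alone), with a median of 0.05 ± 0.13 and a camera adjusted p of 0.822. Without array 1, 23 were higher and 44 lower and the list's median was −0.03, with a camera adjusted p of 0.362. srx-95, srx-84 and srw-85 lay at −3.73 ± 1.24, −2.16 ± 0.60 and −1.81 ± 0.89.

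Of 18 dauer and starvation genes, 12 were lower and 0 higher (12 and 0 adjusted over the list alone), with a median of −0.94 ± 0.13. The dauer is the long-lived larva formed under crowding or hunger. hsp-12.6 and cut-1, already given, and dod-3 at −3.29 ± 0.30 led the list. Camera gave an adjusted p of 6.84e-06, with adjusted p = 0.460 with an estimated correlation. The heat shock and chaperone list split, with 6 of 19 higher and 6 lower (6 and 6 adjusted over the list alone; camera adjusted p = 0.341). The small heat shock genes hsp-12.6 and hsp-12.3 lay at −4.96 ± 0.53 and −3.09 ± 0.33, and hsp-70 at −2.15 ± 0.13. Among the 6 that were higher, named after their values were seen, were the constitutive chaperone genes hsp-110 at 1.77 ± 0.26 and hsp-1 at 1.63 ± 0.33, and the endoplasmic reticulum chaperone genes hsp-4 and hsp-3 at 1.32 ± 0.16 and 1.06 ± 0.34.

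Somatic tissues other than neurons and epidermis showed members in both directions. In the intestine list, 13 of 41 genes were higher and 7 lower (14 and 8 adjusted over the list alone; median 0.05 ± 0.04; camera adjusted p = 0.489). The acyl-CoA dehydrogenase gene acdh-1 was higher at 3.27 ± 0.63, and the metallothionein gene mtl-1 and the ferritin gene ftn-1 were lower at −2.88 ± 0.89 and −2.56 ± 0.31. The intestine median lay between 0.02 and 0.12 with 1 array left out. In body wall muscle, 5 of 31 genes were higher and 6 lower (5 and 6 adjusted over the list alone; median −0.09 ± 0.23; camera adjusted p = 0.578). The basement membrane gene unc-52 and the troponin T gene tnt-2 were higher at 1.53 ± 0.58 and 1.12 ± 0.73, and unc-98 was lower at −1.1 ± 0.17. The other 3 that were higher, named after their values were seen, were mup-2, act-4 and unc-60, at 0.68 to 1.02. Without array 3 the muscle list had 2 higher and 6 lower and a median of −0.20, and without array 2 it had 7 and 4 and a median of 0.05. Of 23 genes of the somatic gonad, vulva and uterus, 4 were higher and 5 lower (4 and 5 adjusted over the list alone; median −0.12 ± 0.18; camera adjusted p = 0.770). The nidogen gene nid-1 lay at 1.49 ± 0.17, and the transcription factor genes ceh-18 and lin-29 at −1.0 ± 0.27 and −0.86 ± 0.20. Named after their values were seen, lin-3, inx-9 and inx-8 were higher, at 0.47 to 0.64, and unc-53, lin-11 and egl-26 lower, at −0.73 to −0.54. The gonad list had 1 higher and 4 lower and a median of −0.07 without array 2, and 2 and 3 and a median of 0.01 without array 3. In the pharynx list, 1 of 27 genes was higher and 8 lower (1 and 8 adjusted over the list alone), with a median of −0.35 ± 0.35 and array medians of −0.39, −0.56 and 0.12. The troponin C gene tnc-2, the transcription factor gene peb-1 and phat-5 lay at −2.59 ± 0.44, −2.35 ± 0.56 and −2.15 ± 1.07. The 1 that was higher, named after its value was seen, was tni-4 at 0.58 ± 0.24. The pharynx counts were 2 higher and 10 lower without array 1, 0 and 8 without array 2, and 0 and 11 without array 3, with medians of −0.15, −0.16 and −0.45. The list passed by camera (adjusted p = 0.00951), had adjusted p = 0.524 with an estimated correlation, and did not pass once the mean of neighbouring probes was taken out (adjusted p = 0.105). Of 55 histone genes, 1 was higher and 13 lower (1 and 13 adjusted over the list alone), with a median of −0.21 ± 0.08, led by his-71 at −1.64 ± 0.39, his-37 at −1.14 ± 0.36 and his-24 at −1.08 ± 0.33. The 1 that was higher, named after its value was seen, was his-47 at 0.64 ± 0.29. The histone counts were 3 higher and 16 lower without array 1, 1 and 8 without array 2, and 0 and 7 without array 3. Camera gave an adjusted p of 0.0120 for the histones, with adjusted p = 0.524 with an estimated correlation, and 0.159 without array 2.

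**Figure D3:**
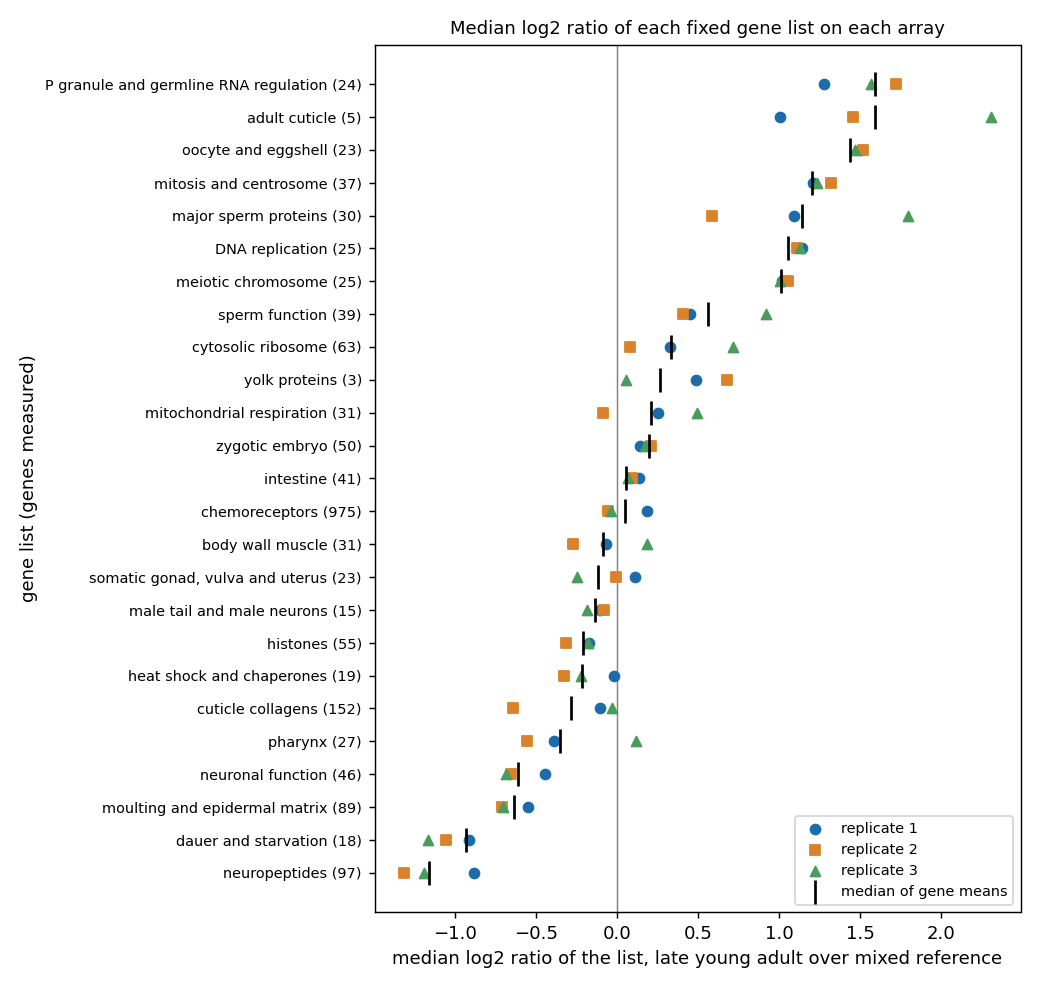
Median log2 ratio of each of 25 fixed gene lists on each array (coloured points, 1 per replicate), with the median of the gene means as a black mark and the number of measured genes in parentheses. The oocyte, meiotic, replication and mitosis lists lie close together on all arrays, while the major sperm proteins run from 0.59 on array 2 to 1.80 on array 3.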

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

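The 7393 genes past the threshold became 7352 to 7456 under centring, scaling or quantile normalization of the arrays, 7577 with the mean of neighbouring probes taken out, 6925 when centred on the chemoreceptors and 9415 with quality weights; these last 3 settings were chosen after seeing the data. Of the 7393, 7201 to 7350 were called again, in the same direction, under the first 3 settings, and 6356 with neighbouring probes taken out. The unmoderated one-sample test called 0 genes (0 higher, 0 lower, 0 at least 2-fold), with 6188 at an unadjusted p under 0.05. At an adjusted p under 0.01, 4903 passed, 2492 higher and 2411 lower. Leaving out 1 replicate gave 5352 to 8458 genes, 2676 to 4274 higher and 2676 to 4184 lower, and 3058 to 3834 at least 2-fold against 3299; the lowest count was without replicate 3 and the highest without replicate 1. Of the 7393, 6965 were called again in the same direction without replicate 1, 5687 without replicate 2 and 5200 without replicate 3. The 86 genes named by the rule fixed in advance kept their direction and their side of the threshold under centring, scaling, quantile normalization, robust eBayes and each left-out replicate. That rule took the largest ratios past the threshold, so their stability says little about the other called genes. Genes named outside the rule were not part of this count. The mean correlation of the arrays was 0.936 over genes of at least 2-fold, which are selected by their mean, against 0.812 over all.

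Of the 16 lists camera called, 0 passed with an estimated correlation (3 at an unadjusted p under 0.05) and 9 passed by fry, which called 10 in all. With 3 arrays the estimated correlation setting could hardly pass a list, so its failures by themselves decide nothing about a list. The estimates themselves differed between the called lists. They were −0.00764 to 0.0144 for the P granule, oocyte and meiotic lists. For the adult cuticle, major sperm protein and ribosome lists they were 0.890, 0.789 and 0.612, and for the other called lists 0.0676 to 0.242. Where the estimate lay well above the preset of 0.01, the preset camera p may be far too small. With an estimated correlation the adjusted p was 0.218 for the oocyte, P granule and meiotic lists, 0.337 for replication and mitosis, 0.390 for moulting, 0.398 for neuropeptides, 0.460 for dauer and starvation, 0.524 for the major sperm proteins, sperm function, adult cuticle, pharynx, neuronal function and histones, 0.775 for the ribosome and 0.790 for collagens. By fry the adjusted p was 0.107 for the major sperm proteins, 0.0794 for sperm function, pharynx and histones, 0.0780 for the adult cuticle, 0.268 for the ribosome and 0.477 for collagens, while the yolk proteins passed at 0.0368. The collagen list also missed the threshold with centring (0.0641), scaling (0.0748), genes on at least 2 arrays (0.136), ranks (0.0537) and neighbouring probes taken out (0.0582), where the pharynx had 0.105; the histones missed it with genes on at least 2 arrays (0.0583). Without 1 replicate the adjusted p ran from 0.000825 to 0.274 for collagens, 0.000300 to 0.194 for the ribosome, 0.0122 to 0.569 for mitochondrial respiration and 0.0101 to 0.159 for histones. The cause was not tested. Member counts moved by over 1.5 times in at least 1 direction without 1 replicate in the male, zygotic embryo, moulting, pharynx, chemoreceptor, histone, somatic gonad, ribosome, respiration, sperm function and body wall muscle lists, several of them counts of few genes; the sperm function list went from 21 to 9 higher and the ribosome from 15 to 3 without replicate 3. No paired analysis was possible because the series has 1 group. Without intensities, a small ratio of a faint spot cannot be told from no difference.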

Other observations

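The tests on position, on the germline lists, on spe- genes, on cuticle members and on sign assignments were chosen after the result was seen; those on print order, housekeeping genes and the second dauer list were written before. Grouping genes by the stem of their symbol, also chosen after seeing the data, gave 149 families of at least 10 measured genes. Camera called 51 of them after Benjamini-Hochberg adjustment, 19 higher and 32 lower. By camera with an estimated correlation 0 passed (smallest adjusted p = 0.653, 2 families at an unadjusted p under 0.05), a setting that could hardly pass a family with 3 arrays. Nuclear pore genes (npp) stood out, with 20 of 21 higher and a median log2 ratio of 1.18 ± 0.19 (SD of array medians), led by npp-9 at 2.31 ± 0.15. Of 13 genes of the proteasome's regulatory particle (rpn) 11 were higher, with rpn-1 at 1.77 ± 0.04, as were 12 of 19 translation initiation factor genes (eif) and 8 of 11 splicing genes (prp), with 0 lower in each. In the lower direction, 28 of 46 transthyretin-related genes (ttr) passed, with a median of −0.84 ± 0.15 and ttr-27 at −3.28 ± 0.37, and 2 were higher, ttr-14 at 0.74 ± 0.38 and ttr-58 at 0.73 ± 0.46. Of 25 globin genes (glb) 16 were lower and 0 higher, of 40 neuropeptide receptor genes (npr) 16 and 0, and of 235 nuclear hormone receptor genes (nhr) 74 and 7.

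Some paralogue pairs of ribosomal and respiratory proteins, among 8 pairs picked after the gene values were seen, differed in their ratios. The 2 ribosomal protein genes that were lower, rpl-11.2 and rpl-23A.1, have the same base name as the 2 that led the list, rpl-11.1 and rpl-23A.2. Within arrays, rpl-11.1 exceeded rpl-11.2 by 1.82 ± 0.28 (SD, n = 3) and rpl-23A.2 exceeded rpl-23A.1 by 1.91 ± 0.40 on the log2 scale. Likewise asb-1 exceeded asb-2 by 1.38 ± 0.36, asg-1 exceeded asg-2 by 1.32 ± 0.59, cyc-2.2 exceeded cyc-2.1 by 1.20 ± 0.27, and ucr-2.3 exceeded ucr-2.1 by 1.41 ± 0.74 and ucr-2.2 by 1.22 ± 0.26, each on 3 of 3 arrays. rpl-37.1 and rpl-37.2 differed by −0.03 ± 0.15. These differences were taken within each array and not tested.

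The ribosomal, respiratory and sperm lists ranked the arrays alike, highest on array 3 and lowest on array 2. A bias that goes with transcript abundance could account for the gap between arrays 2 and 3. There, 38 of 38 abundant housekeeping genes were higher on array 3, by a median of 0.706. This was close to the 0.647 of ribosomal and the 0.660 of respiratory genes. The list of 3 yolk protein genes, abundant in adults, went the other way, with a median on array 3 minus that on array 2 of −0.627 (vit-2 lay higher on array 3), so abundance alone leaves it unaccounted for. The major sperm proteins differed by 1.21 (95% bootstrap interval 1.09 to 1.33), more than the housekeeping genes (0.574 to 0.818). These intervals resample genes on 1 pair of arrays and hold no spread between preparations. The sperm protein genes may also share signal, so they are not independent draws. The place of array 1 in the ranking was not tested in this way. Between arrays 3 and 1 the housekeeping genes went both ways, although more of them were higher on array 3. The major sperm protein medians were 1.80 on array 3 and 1.09 on array 1. That gap was not set against the housekeeping genes. Whether part of the sperm protein difference needs another account therefore stays open. More sperm in preparation 3 may add to it. Over the 12 spe- genes of the sperm function list the difference was 0.114 with an interval of −0.137 to 0.342. Over the other 27 sperm function genes it was 0.698 (0.396 to 1.11), which leaves that open. All 23 measured spe- genes were not compared in this way, and the SD of their array medians was 0.09.

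Array 1 correlated less with the others. Position on the array is a candidate explanation for part of this. No print layout was used, so the order of the probe numbers was assumed to follow the print. The mean of 56 neighbouring probes, at distances set by hand along these numbers, accounted for 17.3% of the variance of array 1 minus the others. For array 2 minus array 3 it accounted for 4.87%. Taking a running median of 97 probes out of each array raised the mean correlation from 0.765 to 0.788, a rise of 0.0231 (0.0140 to 0.0321), so most of the gap to the 0.899 between arrays 2 and 3 remained and its cause stays open. A different germline stage of preparation 1 cannot be told apart from these: over 134 germline genes array 1 lay at −0.0999 (−0.161 to −0.0363) from the others. The list medians differed by −0.365 for P granule genes, 0.0137 for oocyte, −0.0136 for meiotic, 0.0257 for replication and −0.0661 for mitosis genes. Lists outside the germline differed by as much, with 0.370 for neuropeptide and insulin-like and −0.879 for adult cuticle genes. In the P granule, neuropeptide and adult cuticle lists the array 1 median was the one nearest to 0.

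The dauer and starvation list was lower in adults by camera (adjusted p = 6.84e-06; adjusted p = 0.460 with an estimated correlation). Dauer or fasted larvae in the reference RNA may account for it: a second list of 16 dauer and fasting genes had a median of −0.796, below all of 10000 random lists of its size (not matched on intensity), with 9 genes lower, such as the fasting-induced lipase gene fil-1 at −3.49 ± 0.11 and the trehalose synthase gene tps-1 at −1.51 ± 0.31. That list was mixed, with gpdh-1 at 1.82 ± 0.23 and lipl-5 at 2.23 ± 0.40 higher, and its bootstrap interval of −1.36 to 0.0115 reached 0. Its lower genes also held the collagens col-2 at −3.63 ± 1.75 and col-40 at −0.92 ± 0.93, so it was not free of cuticle genes. Cuticle renewal by larvae in the reference stays open too. Only 2 of the 18 genes of the first list were cuticle or secreted members. The median of −0.770 (−2.04 to −0.353) without them could therefore hardly have moved. Expression of these genes in fed larvae was not tested, since the labels do not give the make-up of the reference.

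With 3 arrays and 1 group, turning the sign of an array gives only 4 assignments, too few for a share under 0.05. The real one, 1 of the 4, gave 7393 genes and the highest of the others gave 0.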
